A study of Homo sapiens with 6 samples.

How the data were processed

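RNA sequencing libraries of total RNA from PC9ER cells, a human lung cancer line, were analysed, 3 from vehicle-treated control cells and 3 from cells given gefitinib. Per the labels, cells grew in medium with 10% fetal calf serum. The one protocol given for all samples has 72 h of DMSO vehicle in place of the Notch inhibitor, serum withdrawal overnight and 1 µM gefitinib for the last 6 h, and does not say whether control cells were also without serum or how they were handled in those 6 h. RNA was extracted with a column kit and sequenced with standard Illumina libraries. The series' design text also names a Notch inhibitor alone and in combination; such cells were not analysed here. The submitters' processing notes name STAR, HTSeq and the GRCh38 genome, without versions; whether counting used the strand of the reads is not given in the sources used here, so reads where genes overlap on opposite strands are of uncertain origin.

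The deposited table of coding genes holds a never-negative signal, gene read counts that the authors scaled to a common total of 18085800 per library. Its values are whole multiples of 1 step per library: with a tolerance of 0.01 read, 100% of the values above 0 came out as whole reads, which gave the coding reads per library, from 13674237 to 38581498; on these reads edgeR called 3707 genes higher and 3752 lower of 12167 tested. Of 15376 rows, 147 were 0 in every library and 15229 were tested. Another deposited table holds 6 per-sample columns of counts whose names match no label; these columns are not used, and only the gene IDs, symbols and positions of that table served to look up genes. A single gene ID was found for 15356 rows and not for 20; 99.7% of the rows had an ID in GENCODE release 29 (GRCh38), and for 95.9% of those the position in the table equals the GENCODE start. Coordinates are from GENCODE. In the deposited list of genes, 27 symbols had been turned into dates, of which 2 stand on more than 1 row, and none of these is named.

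Samples were grouped by their titles. The design fixed before the data were examined assumed raw counts and edgeR's quasi-likelihood test. The table with labelled columns holds scaled counts, so the reported test is limma-trend 3.58.1 (R 4.3.3) on log2(value + 1), 2-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05; edgeR 4.0.16 on the recovered reads was added after the data were seen. Log2 differences are gefitinib minus control on the log2(value + 1) scale, which understates the change of low genes, and carry their standard error. For genes with 1 to 3 reads in a group, the ratio of reads with an exact 95% interval is given; it covers counting error only.

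The 27 gene lists were also fixed before the data were examined: MAP kinase output, immediate early genes, Notch targets, Notch machinery, STAT3 targets, EGFR family and ligands, other receptor kinases, BCL2 family, FOXO targets, S phase, mitosis, glycolysis, cholesterol synthesis, interferon response, YAP and TEAD targets, integrated stress response, p53 targets, inflammatory NF-kappa-B genes, ribosome biogenesis, epithelial, mesenchymal, neuroendocrine, squamous, fibroblast and blood markers, mitochondrial transcripts, cytosolic ribosomal proteins and housekeeping genes. Each was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members were counted as higher, lower or not past the threshold, adjusted over all genes and over the list alone. The named genes follow a rule of the same date: the 12 largest rises and 12 largest falls among genes past the threshold with a mean of 5 CPM (reads scaled to library size) or more and groups that do not overlap, up to 4 members of each list with the smallest p, and EGFR, ERBB2, ERBB3, MET, AXL, HES1, HEY1, NOTCH1, NOTCH3, JAG1, STAT3 and BCL2L11; this gives 135 genes. Genes named outside it to complete a short count are marked as named after their values were seen.

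The alternatives fixed beforehand were pseudocounts of 0.5 and 5, a mean value of 10 or more, at least 1 CPM in 3 libraries, TMM factors, DESeq2 size factors, DESeq2 1.42.0 and limma-voom on the recovered reads, a test against a 1.2-fold change, a block for the replicate number with and without removal of a GC or length trend, and leaving out each library. Added after the data were seen were edgeR with and without a count filter, removal of the GC or length trend without the block (loess, span 0.3), and library totals without mitochondrial transcripts. No 2 libraries of a group agreed within sampling noise. The test was tried on simulated data for gefitinib against control, with 200 genes changed by known amounts: 32.8% of 67 genes changed 1.5-fold, 95.5% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered, and 10 unchanged genes were called among 14488 genes tested. In that simulation the changed genes were drawn only from genes above a minimum control mean, so recovery of low genes was not tried. All simulated genes shared a dispersion of 0.0175, so the count of unchanged genes called does not cover genes or libraries that vary more. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.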

Results

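Messenger RNA was measured by RNA sequencing in PC9ER cells, a human non-small cell lung cancer line driven by the receptor tyrosine kinase EGFR and resistant to the EGFR inhibitor gefitinib. The 6 libraries form 2 groups of 3: control cells that received the vehicle DMSO, and cells given 1 µM gefitinib for the last 6 h. One protocol with overnight serum withdrawal is given for all samples, and the labels do not state the serum state of the control cells, so a difference in serum between the groups is not excluded for any result below. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these 3 and 3 libraries, which may be technical. Control libraries 1, 2 and 3 held 25639050, 16211544 and 18736157 reads in coding genes, and gefitinib libraries 1, 2 and 3 held 13674237, 20013453 and 38581498. Between 13746 and 14567 of the 15376 coding genes had reads in a library, and the 10 most abundant genes took between 2.86% and 3.70% of the reads. Principal component 1 of the log2 values held 85.7% of the variance and separated the groups, with control libraries at -52.0, -51.8 and -51.2 and gefitinib libraries at 43.0, 53.8 and 58.1. Component 2 held 8.22% and set control replicate 1, at 30.5, apart from control replicates 2 and 3, at -9.29 and -22.1.

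The comparison asks how the transcriptome of these resistant cells differs after a short exposure to the EGFR inhibitor. EGR1 and FOS, transcription factor genes of the growth factor response, rose with gefitinib, EGR1 from a normalized read count of 75.7 ± 21.1 (SD, n = 3) to 6290 ± 820 and FOS from 406 ± 32.4 to 2489 ± 437. MYC fell from 3569 ± 317 to 687 ± 89.9, the chemokine gene CXCL8 from 182 ± 14.5 to 7.30 ± 6.27 and EGFR itself from 31425 ± 3059 to 15759 ± 247. BCL2L11, which encodes the pro-apoptotic protein BIM, rose from 662 ± 50.2 to 2509 ± 356. BCL2L1, which encodes the survival protein BCL-XL, fell from 3867 ± 446 to 1188 ± 150. Of 15229 genes tested, 4312 were higher and 3473 lower with gefitinib at a limma adjusted p under 0.05, of which 1887 rose and 1510 fell at least 2-fold. The normalized values of the groups did not overlap for 58.0% of the tested genes, against 10% by chance for 3 libraries against 3. On the recovered reads, edgeR called 3707 genes higher and 3752 lower of 12167 tested. The median log2 difference over all tested genes was 0.10 with the deposited scaling and 0.04 with TMM factors. The share of calls that were higher was 55.4% and 50.4%, so small changes in 1 direction depend on the scaling.

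**Figure D1:**
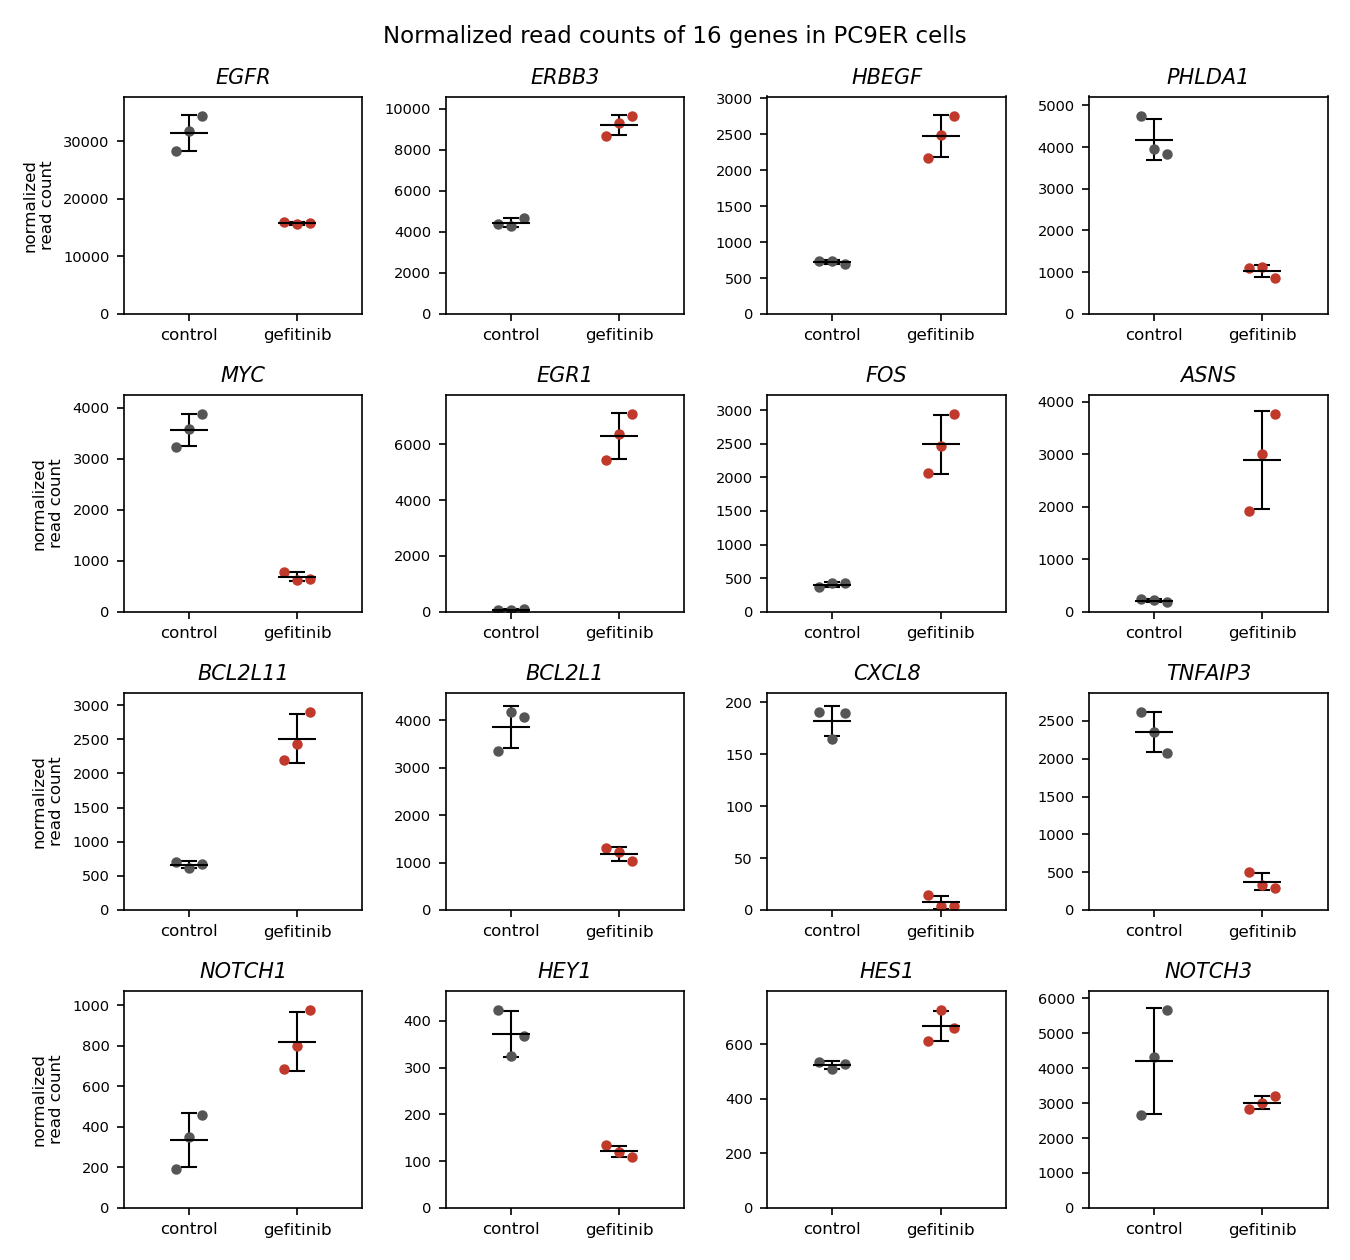
Normalized read counts (vertical axes, linear, each starting at 0) of 16 genes in PC9ER cells given vehicle (control) or gefitinib. Each point is 1 of 3 libraries per group, the long bar is the group mean and the whiskers are ± 1 SD; the 3 gefitinib libraries lie on one side of the 3 control libraries for each gene shown except NOTCH3, whose means are 4207 and 3008.

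Among the 12 genes with the largest rises were several transcription factor genes. NR4A3, an orphan nuclear receptor gene (chromosome 9, 99821855 to 99866891, GRCh38), had 1 read in the 3 control libraries together and 922 in the 3 gefitinib libraries, a depth-corrected ratio of 773 with a 95% counting interval from 138 to 30563. EGR1 (chromosome 5, 138465490 to 138469315) rose by 6.38 ± 0.19 (SE) on the log2 scale (limma adjusted p = 2.07e-07) and EGR2 (chromosome 10, 62811996 to 62919900) by 5.06 ± 0.26. The others were PYGM, the muscle glycogen phosphorylase gene, at 6.24 ± 0.45, KIAA1683 at 6.22 ± 0.33, HCLS1, a gene best known from blood cells, at 5.95 ± 0.65 and SESN3, a stress-responsive sestrin gene, at 5.83 ± 0.32. Further down were FAM46C at 5.18 ± 0.16, AOC3 at 4.85 ± 0.24, EFR3B at 4.51 ± 0.28, TRIM36 at 4.08 ± 0.27 and ZCCHC24 at 3.99 ± 0.25. FAM46C went from 76.3 ± 2.55 to 2841 ± 623 normalized reads (n = 3) and SESN3 from 3.44 ± 1.06 to 253 ± 65.7.

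Among the 12 genes with the largest falls, C8orf4 (chromosome 8, 40153455 to 40155308, GRCh38) changed by -5.62 ± 0.24 (SE), from 835 ± 283 to 15.4 ± 0.437 normalized reads (SD, n = 3). INHBA, the activin A subunit gene (chromosome 7, 41667168 to 41705834), changed by -5.23 ± 0.18, from 1438 ± 197 to 37.5 ± 7.62. OLR1, the receptor gene for oxidized low-density lipoprotein, changed by -4.96 ± 0.31, CXCL8 by -4.71 ± 0.46 and TNS4 by -4.42 ± 0.24. NOG, which encodes the BMP antagonist noggin, changed by -4.39 ± 0.18, SYDE1 by -4.38 ± 0.20 and SIX3 by -4.35 ± 0.25. COL15A1 changed by -4.21 ± 0.25, CCRL2 by -4.12 ± 0.15, AMIGO2 by -4.11 ± 0.10 and ANKRD1 by -4.02 ± 0.29. AMIGO2, at a limma adjusted p of 1.55e-07, had means of 4088 and 236 normalized reads, and CCRL2 had 1750 ± 65.8 and 101 ± 18.2.

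The receptor that gefitinib inhibits and its relatives moved in both directions. EGFR (chromosome 7, 55019021 to 55211628, GRCh38) fell by 0.99 ± 0.09 (SE) on the log2 scale (limma adjusted p = 2.14e-05). ERBB3, its kinase-impaired partner receptor (chromosome 12, 56076799 to 56103505), rose by 1.05 ± 0.08 (limma adjusted p = 7.32e-06). ERBB2 had 1306 ± 407 normalized reads in control and 1528 ± 95.3 in gefitinib libraries (SD, n = 3; limma adjusted p = 0.295, and 0.0417 with the GC trend removed, over a range from 0.0165 to 0.991 for all alternatives). HBEGF, which encodes a ligand of EGFR, rose from 727 ± 25.8 to 2474 ± 290, and ERRFI1, a feedback inhibitor of EGFR, fell from 13054 ± 1735 to 4926 ± 257. Of 15 receptors, ligands and regulators of this family tested, 3 rose, 4 fell and 8 did not pass the test, with the same counts adjusted over the list alone. The remaining calls were AREG, higher by 1.87, and EREG and TGFA, at -1.35 and -1.13; these ligand genes were named after their values were seen. The list as a whole did not differ from other genes (camera adjusted p = 0.877), and its median of 0.28 and mean of 0.04 are above 0 while the direction of the set test is down. Of 14 other receptor kinases, 4 rose, 5 fell and 5 did not pass (the same adjusted over the list alone; camera adjusted p = 0.877, direction down, median 0.13, mean 0.08). FGFR1 rose from 49.1 ± 15.4 to 356 ± 101 and INSR from 362 ± 15.5 to 836 ± 41.7. MET fell from 4390 ± 243 to 2761 ± 87.2, ROR1 from 1161 ± 40.1 to 485 ± 45.1 and AXL from 96.8 ± 24.2 to 31.1 ± 1.72.

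Transcripts that report on MAP kinase signalling were mostly lower. PHLDA1, the receptor gene EPHA4, the cyclin gene CCND1 and the ERK phosphatase gene DUSP4 fell, with PHLDA1 going from 4177 ± 492 to 1029 ± 139 normalized reads and DUSP4 from 2931 ± 151 to 1385 ± 93.6 (SD, n = 3). CCND1 went from 4478 ± 156 to 2098 ± 171 and EPHA4 from 1550 ± 114 to 476 ± 51.9. Of 18 members of this list, 10 fell, 4 rose and 4 did not pass, with the same counts adjusted over the list alone. The risers, named after their values were seen, were SPRED3 at 1.62, SPRY2 at 1.21, ETV5 at 0.65 and SPRY4 at 0.53. The SPRED and SPRY genes encode feedback inhibitors of the pathway and did not move together: SPRY1 and SPRED2 fell, at -1.29 and -1.12, and SPRED1 had a difference of 0.06 (limma adjusted p = 0.781). SPRY1, SPRED2 and SPRED1 were also named after their values were seen. The list was lower by camera (adjusted p = 0.0184), a call that was lost with an estimated correlation (adjusted p = 0.707 with an estimated correlation).

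Immediate early genes, the fast responders to growth factors and stress, moved mainly the other way. Of 24 members, 15 rose, 3 fell and 6 did not pass, the same counts as adjusted over the list alone, and EGR1, EGR2, FOS and MYC had the smallest p. ATF3, FOSB and NR4A2, named after their values were seen, rose by 3.34, 2.95 and 1.91. MYC fell by 2.38 ± 0.11 (SE) on the log2 scale. The other members that fell, named after their values were seen, were KLF6 and JUN, at -1.15 and -0.65. The list was higher by camera (adjusted p = 0.0203; adjusted p = 0.707 with an estimated correlation). Serum itself acts on these genes, and the serum state of the control cells is not given.

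The series concerns Notch signalling beside EGFR, and Notch genes moved in both directions. NOTCH1 rose from 334 ± 134 to 821 ± 146 normalized reads (SD, n = 3; limma adjusted p = 0.00289) and the ligand gene JAG1 from 694 ± 62.3 to 1097 ± 121. DLL4, another ligand gene (chromosome 15, 40929333 to 40939073, GRCh38), had 3 reads in all control libraries and 267 in all gefitinib libraries, a ratio of 74.6 with a 95% counting interval from 25.3 to 364. The Notch effector gene HEY1 fell from 372 ± 48.6 to 121 ± 12.2, whereas HES1, the effector most often used as a readout, had 524 ± 13.8 and 666 ± 55.9. The HES1 difference of 0.34 ± 0.11 (SE) had a limma adjusted p of 0.0224 that became 0.0692 with TMM factors, and 0.0874, 0.122 and 0.0626 without control replicate 2, gefitinib replicate 2 or gefitinib replicate 3, over a range from 0.00480 to 0.416 for all alternatives. The HES1 call was lost in 11 alternatives, among them edgeR (adjusted p = 0.0579), DESeq2 (0.0718) and limma-voom (0.0526) on the recovered reads. NOTCH3 had 4207 ± 1507 and 3008 ± 182 (limma adjusted p = 0.153), and without control replicate 1 the adjusted p was 0.000292, with a range from 0.000247 to 0.456 over the alternatives. NOTCH3 was called lower in 7 alternatives, among them edgeR (adjusted p = 0.0388), DESeq2 (0.0115) and the GC trend removed (0.000784). Of 15 members of the Notch target list, 7 rose, 3 fell and 5 did not pass (7 and 4 adjusted over the list alone, camera adjusted p = 0.877). With TMM factors 6 rose and 4 fell, and edgeR called 6 higher and 5 lower of 14 tested. The list was fixed beforehand, and whether Notch acts on its members in these cells was not tested. Among the list members HES6 rose by 2.35 ± 0.26, while GATA3 and BHLHE40 changed by -2.04 ± 0.14 and -0.97 ± 0.10. Of 24 ligands, receptors, proteases and cofactors of the pathway, 11 rose, 5 fell and 8 did not pass (the same adjusted over the list alone, camera adjusted p = 0.734). For these genes edgeR called 9 higher and 6 lower of 20 tested, and without control replicate 1 the counts were 9 and 6. The coactivator genes MAML1 and MAML2 moved apart, MAML1 by 0.92 ± 0.09 and MAML2 by -1.72 ± 0.10, and PSEN2, a subunit gene of the protease that releases active Notch, fell from 929 ± 185 to 490 ± 6.50.

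Genes of cytokine signalling through STAT3 were split. LIF, an interleukin-6 family cytokine gene, fell from 2993 ± 333 to 332 ± 111 normalized reads (SD, n = 3) and CEBPB from 1546 ± 64.7 to 540 ± 45.7. The receptor gene IL6R rose from 15.8 ± 5.97 to 232 ± 16.1 and the kinase gene PIM2 from 178 ± 14.8 to 585 ± 100. Of 17 members, 4 rose, 7 fell and 6 did not pass (5 and 8 adjusted over the list alone). The camera adjusted p was 0.364 with direction down, the median -0.13 and the mean 0.02. STAT3 itself had 3492 ± 121 and 3219 ± 580 (limma adjusted p = 0.392, and 0.0335 without gefitinib replicate 1, over a range from 0.0335 to 0.981 for all alternatives).

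Genes of inflammatory signalling through NF-kappa-B were among the most uniformly lower. TNFAIP3, a feedback inhibitor of NF-kappa-B, fell from 2352 ± 266 to 371 ± 112 normalized reads (SD, n = 3), BIRC3 from 2690 ± 719 to 400 ± 104 and NFKBIA, the inhibitor I-kappa-B alpha, from 1073 ± 39.2 to 467 ± 39.4. Of 19 members, 13 fell, 1 rose and 5 did not pass, with the same counts adjusted over the list alone; the riser was TNF at 1.56, named after its value was seen, with means of 1.11 and 4.68 normalized reads. The camera adjusted p was 0.000319 (adjusted p = 0.648 with an estimated correlation), and among the 9 members that edgeR tested after its count filter 9 fell. Interferon response genes did not move together: of 21, 5 rose, 5 fell and 11 did not pass (the same adjusted over the list alone; camera adjusted p = 0.877, direction down, median 0.37, mean 0.06). Several of these genes had few reads. Among the 14 that edgeR tested after its count filter, 4 rose and 6 fell, with a median of -0.29. IFIT3 and IFIT1 changed by -2.74 ± 0.30 and -2.60 ± 0.37 (SE), and STAT2 rose by 0.77 ± 0.10. IFI27, with 1.25 ± 0.624 and 11.1 ± 4.22 normalized reads, rose from a very low level.

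The integrated stress response, a programme driven by the transcription factor ATF4, was largely higher. ASNS, which encodes asparagine synthetase, rose from 215 ± 30.7 to 2895 ± 928 normalized reads (SD, n = 3), SESN2 from 294 ± 19.6 to 1513 ± 395 and PPP1R15A, which restores translation after stress, from 2200 ± 57.3 to 6519 ± 325. TRIB3, a pseudokinase gene of the same programme, fell from 3630 ± 51.3 to 1131 ± 160. Of 19 members, 14 rose, 2 fell and 3 did not pass, with the same counts adjusted over the list alone; the other faller was SLC7A11 at -0.41, named after its value was seen. The camera adjusted p was 0.00197 (adjusted p = 0.707 with an estimated correlation). Targets of p53 were mixed, with 7 of 15 higher, 6 lower and 2 not past the threshold (the same adjusted over the list alone; camera adjusted p = 0.907, direction down, median 0.31, mean 0.06). CDKN1A, the p21 cell cycle inhibitor gene, rose by 1.41 ± 0.14 (SE) and RRM2B by 0.90 ± 0.10, while FAS and AEN changed by -1.60 ± 0.21 and -1.14 ± 0.13.

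Among genes that control cell death, BCL2L11 (chromosome 2, 111119378 to 111168447, GRCh38) rose by 1.91 ± 0.12 (SE) on the log2 scale and BMF, another pro-apoptotic member, by 2.03 ± 0.23. BCL2L1 (chromosome 20, 31664452 to 31723989) and the pro-apoptotic BID changed by -1.70 ± 0.12 and -0.88 ± 0.12. Of 15 BCL2 family members, 6 rose, 5 fell and 4 did not pass (the same adjusted over the list alone; camera adjusted p = 0.877). Targets of FOXO transcription factors, which growth factor signalling restrains, were higher for 12 of 19 members, lower for 4 and not past the threshold for 3 (12 and 5 adjusted over the list alone; camera adjusted p = 0.197). KLHL24 rose from 1283 ± 186 to 7556 ± 221 normalized reads (SD, n = 3) and the ubiquitin ligase gene FBXO32 from 771 ± 100 to 2459 ± 163. IRS1, which encodes an insulin receptor adaptor, fell from 1181 ± 168 to 115 ± 9.73.

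Genes of the cell cycle did not fall as a group. Of 21 S phase genes, 10 rose, 5 fell and 6 did not pass (11 and 5 adjusted over the list alone, and 6 and 5 over all genes with TMM factors; camera adjusted p = 0.484). Without gefitinib replicate 1 the S phase counts were 10 higher and 2 lower, and without control replicate 1 they were 10 and 6. CCNE2 rose from 278 ± 30.9 to 1153 ± 77.4 normalized reads (SD, n = 3) and PCNA from 4287 ± 255 to 7722 ± 78.8. RRM2, a ribonucleotide reductase subunit gene, fell from 6635 ± 645 to 2502 ± 441 and CCNE1 from 1013 ± 58.7 to 539 ± 120. In the list Mitosis genes, 20 were tested, of which 12 rose, 3 fell and 5 did not pass (13 and 3 adjusted over the list alone). The kinesin gene KIF11 rose by 1.27 ± 0.08 (SE), BIRC5, which encodes survivin, by 1.58 ± 0.15, KIF20A by 0.96 ± 0.07 and CENPF by 0.50 ± 0.07. The fallers, named after their values were seen, were CDC20, UBE2C and CCNB1 at -0.38, -0.30 and -0.25. The mitosis list was higher by camera (adjusted p = 0.0379; adjusted p = 0.707 with an estimated correlation). That call was also lost with TMM factors (adjusted p = 0.0704), without control replicate 2 (0.0592) and without gefitinib replicate 1 (0.103), over a range from 0.0141 to 0.103 for the alternatives with the preset correlation.

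Metabolic genes were lower in part. The glucose transporter gene SLC2A3 fell from 7164 ± 660 to 1754 ± 139 normalized reads (SD, n = 3), and the hexokinase genes HK1 and HK2 from 4558 ± 278 to 2282 ± 60.0 and from 4377 ± 73.0 to 2788 ± 80.5. PFKFB3, whose product activates glycolysis, rose from 747 ± 92.7 to 1746 ± 210. Of 19 glycolysis genes, 1 rose, 9 fell and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.707 with an estimated correlation). The glycolysis counts were 1 higher and 12 lower by edgeR, 2 and 14 without control replicate 1, and 1 and 9 without gefitinib replicate 1. Of 18 cholesterol synthesis genes, 3 rose, 8 fell and 7 did not pass (the same adjusted over the list alone; camera adjusted p = 0.338). These counts depended on single libraries, with 3 higher and 4 lower without gefitinib replicate 1, and 5 and 8 without control replicate 1. FDPS, SQLE and FDFT1, enzyme genes of the pathway, changed by -0.98 ± 0.09, -0.84 ± 0.09 and -0.46 ± 0.07 (SE).

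Genes for making ribosomes and genes for the ribosomal proteins themselves moved in opposite directions. Of 20 ribosome biogenesis genes, 13 fell, 2 rose and 5 did not pass (14 and 2 adjusted over the list alone). POLR1B, a subunit gene of RNA polymerase I, fell from 1819 ± 25.5 to 689 ± 49.3 normalized reads (SD, n = 3), MYBBP1A from 1393 ± 388 to 222 ± 17.8 and UTP20 from 1996 ± 77.0 to 1040 ± 36.7. The risers, named after their values were seen, were PES1 at 0.76 and NPM1 at 0.31. With TMM factors and by edgeR, 1 of the 20 rose and 14 fell. NOP2, a nucleolar methyltransferase gene, had 2702 ± 101 and 1000 ± 40.3, but 54.4% of its exonic sequence overlaps another gene. The list was lower by camera (adjusted p = 0.000319; adjusted p = 0.370 with an estimated correlation). Of 25 cytosolic ribosomal protein genes, 20 rose, 0 fell and 5 did not pass, the same adjusted over the list alone, with 21 higher and 0 lower at an unadjusted limma p under 0.05. RPS4X rose from 16709 ± 731 to 23337 ± 387 and RPL15 from 7110 ± 74.6 to 9741 ± 110; RPL10 and RPS2 rose by 0.90 ± 0.09 and 0.70 ± 0.10 (SE). The camera adjusted p was 0.000449 (adjusted p = 0.707 with an estimated correlation). With TMM factors 16 rose and 0 fell, and edgeR called 17 higher and 0 lower.

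**Figure D2:**
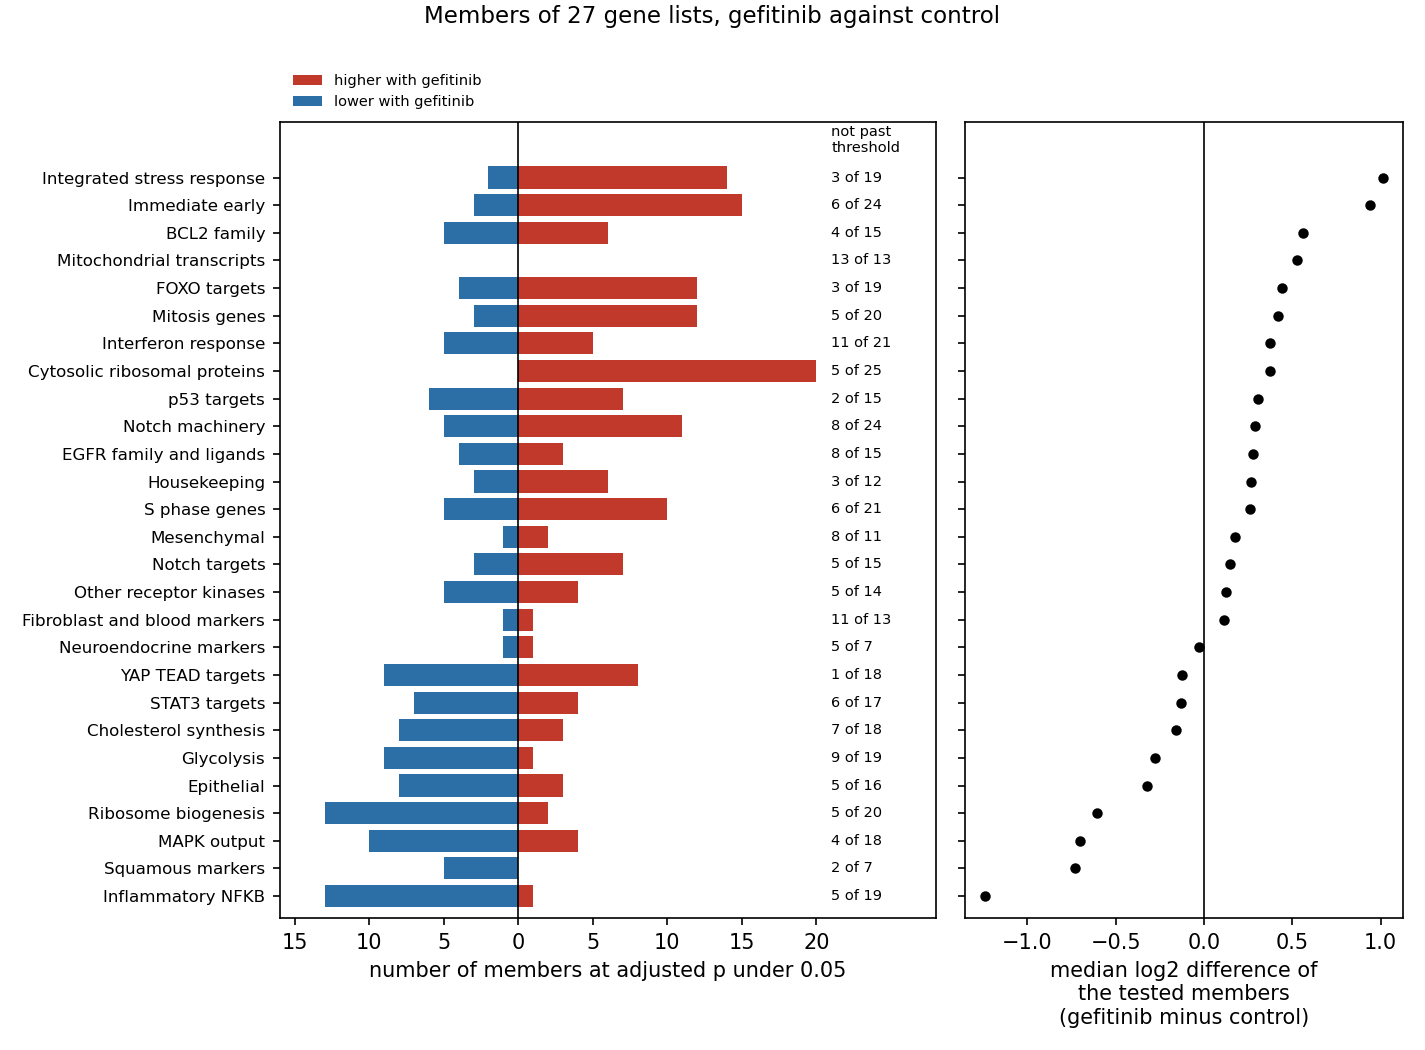
Left, the number of members of each of 27 gene lists that were higher (right of 0) or lower (left of 0) with gefitinib at a limma adjusted p under 0.05, with the number not past that threshold of those tested; right, the median log2 difference (gefitinib minus control) of the tested members. The lists run from inflammatory NF-kappa-B genes, with 13 of 19 lower, to integrated stress response genes, with 14 of 19 higher, and no list that was higher or lower by camera kept that call with an estimated correlation.

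Targets of the YAP and TEAD regulators were divided, with 8 of 18 higher, 9 lower and 1 not past the threshold (the same adjusted over the list alone; camera adjusted p = 0.488). CYR61 rose from 2331 ± 131 to 5412 ± 29.9 normalized reads (SD, n = 3) and AJUBA from 199 ± 16.4 to 792 ± 64.9. AMOTL1 fell from 12077 ± 544 to 3384 ± 285 and TGFB2, a growth factor gene, from 1341 ± 115 to 143 ± 18.4. Of 16 epithelial genes, 8 fell, 3 rose and 5 did not pass (the same adjusted over the list alone; camera adjusted p = 0.125, and 0.0263 without control replicate 1, over a range from 0.0263 to 0.227). The splicing regulator gene ESRP2 fell from 1614 ± 216 to 390 ± 54.8 and the keratin genes KRT18 and KRT7 from 15976 ± 1798 to 10078 ± 472 and from 21846 ± 5914 to 11556 ± 234. OVOL1 rose by 1.14 ± 0.19 (SE). The other risers, named after their values were seen, were GRHL2 and EPCAM at 0.38 and 0.30. Of 11 mesenchymal genes, 2 rose, 1 fell and 8 did not pass (2 and 0 adjusted over the list alone; camera adjusted p = 0.877). The risers were SNAI1 and SNAI2, transcription factor genes of epithelial-mesenchymal transition, at 2.48 ± 0.32 and 1.48 ± 0.25. LOX changed by -0.38 ± 0.14 (limma adjusted p = 0.0466); its adjusted p lay between 0.0365 and 0.125 without 1 library and rose above 0.05, so that the call was lost, without control replicate 1 or 2 and without gefitinib replicate 1, 2 or 3, over a range from 0.00150 to 0.381 for all alternatives. ITGA5 had 1003 ± 209 and 777 ± 53.7 (limma adjusted p = 0.0869). It was lower in 11 alternatives, among them TMM factors (adjusted p = 0.0292), edgeR (0.0231), DESeq2 (0.0131) and the fit without control replicate 1 (0.000674), over a range from 0.000674 to 0.492.

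Markers of other lineages gave a mixed account. Of 7 squamous markers, 5 fell, 0 rose and 2 did not pass, the same adjusted over the list alone, with 0 higher at an unadjusted limma p under 0.05 and 0 by edgeR. KRT5 fell from 11534 ± 1553 to 6796 ± 121 normalized reads (SD, n = 3), KRT6B from 345 ± 51.9 to 131 ± 17.2 and KRT13 from 17539 ± 5019 to 10271 ± 472, and TP63, the lineage factor, from 19.7 ± 3.54 to 3.47 ± 2.29. The remaining faller, named after its value was seen, was KRT6A at -0.71. Their camera adjusted p was 0.0859, and it was 0.0291 without control replicate 1 and 0.0458 without gefitinib replicate 3, over a range from 0.0238 to 0.117. Of 7 neuroendocrine markers, 1 rose, 1 fell and 5 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.907, direction down, median -0.03, mean 0.02). NCAM1 rose by 0.99 ± 0.15 (SE), and POU2F3 changed by -0.97 ± 0.33 (limma adjusted p = 0.0318, between 0.0104 and 0.103 without 1 library, and above 0.05, so no longer called, without control replicate 1, 2 or 3 or gefitinib replicate 2 or 3). SYP had 41.6 ± 3.45 and 29.4 ± 10.3 (limma adjusted p = 0.177, and 0.0437 without gefitinib replicate 1), and DLL3 had 2.22 ± 2.27 and 3.14 ± 1.98. Of 13 fibroblast, endothelial and blood cell markers, 1 rose, 1 fell and 11 did not pass (the same adjusted over the list alone; camera adjusted p = 0.877, direction down, median 0.11, mean 0.09). Only 3 of these markers passed the count filter of edgeR, which called 0 higher and 1 lower. PECAM1, an endothelial adhesion gene, fell from 1216 ± 80.4 to 122 ± 10.5. CD14, a monocyte gene, had 1 read in all control and 30 in all gefitinib libraries, a ratio of 25.2 with a 95% counting interval from 4.18 to 1026. VWF had 8.64 ± 3.72 and 5.18 ± 3.32 (limma adjusted p = 0.288).

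Transcripts often used as constant references also moved. Of 12 housekeeping genes, 6 rose, 3 fell and 3 did not pass (8 and 3 adjusted over the list alone, and 3 and 3 over all genes with TMM factors; camera adjusted p = 0.484). ACTB fell from 44702 ± 10202 to 26012 ± 1734 normalized reads (SD, n = 3) and YWHAZ from 8019 ± 1032 to 5715 ± 313, and GUSB rose by 0.61 ± 0.12 (SE). Mitochondrial transcripts took 2.34%, 1.82% and 1.07% of the reads in control replicates 1, 2 and 3 and 1.67%, 2.78% and 3.07% in gefitinib replicates 1, 2 and 3. Of 13 such transcripts 0 passed the limma test, also adjusted over the list alone and by edgeR, with 2 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.252). MT-CO2 had 31658 ± 13966 and 49552 ± 14888, MT-CO3 35380 ± 13272 and 55143 ± 18462, MT-ND3 16080 ± 4079 and 21212 ± 3221, and MT-ND5 14986 ± 4722 and 22681 ± 6656. Without control replicate 1 the limma adjusted p was 0.0166 for MT-CO2, 0.0228 for MT-CO3, 0.00945 for MT-ND3 and 0.0190 for MT-ND5, and without gefitinib replicate 1 it was 0.0397 for MT-CO3 and 0.0338 for MT-ND5. Without control replicate 1, 11 of the 13 were higher and the camera adjusted p was 0.0430, and without gefitinib replicate 1, 3 were higher (0.0521), over a range from 0.0430 to 0.695.

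Across the 27 lists, 4 were higher and 4 lower by camera with its preset correlation, and 0 were called with an estimated correlation, where 2 had an unadjusted p under 0.05; fry, which tests whether a set moves on balance one way, called 15. For 16 of the 135 named genes over 10% of the exonic sequence overlaps another gene, so part of their reads could belong to the neighbour: PHLDA1, CCND1, CEBPB, BCL2L11, BCL2L1, CCNE2, RRM2, FDPS, TGFB2, ASNS, NOP2, KRT18, OVOL1, KRT13, RPL10 and RPS2, with the largest share, 55.5%, in RPL10.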

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

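Added after the results were seen were edgeR on the recovered reads, the GC or length trend removed without a block, and the totals without mitochondrial transcripts. The edgeR test itself was the main test of the design fixed beforehand. The reported limma-trend test departs from that design, because the table with labelled columns holds scaled counts. Over 23 alternatives of the gene test, genes higher ranged from 3467 to 4582 without 1 library and from 3707 to 4704 under the other settings, except 2947 in the test against a 1.2-fold change; genes lower ranged from 2861 to 4001 and from 3341 to 4425, except 2424; genes changed at least 2-fold ranged from 3037 to 3576 and from 2671 to 3434. No gene called in the reported test was called with the opposite sign under any of these. Of the 135 named genes, 121 kept their side of the threshold in every alternative that tested them, and none changed sign. Most of these genes were picked for large changes or small p in the same data, so their stability does not describe all genes. Of the 7785 calls, between 6253 (without gefitinib replicate 2) and 7476 (without control replicate 1) were kept with 1 library left out. For the lists, 624 of 670 results kept direction and call, 19 lost and 14 gained a call, and 13 turned direction, with 0 of these past the threshold. The 2 alternatives "total count only" and "only coding genes" were not run, because the table is already scaled to totals and limited to coding genes.

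With an estimated correlation the MAP kinase output and immediate early lists had adjusted p = 0.707. With fry the STAT3 target list had adjusted p = 0.0177, in a test of the list's own genes only. Directions that turned, all without a call, were Notch targets with DESeq2 (adjusted p = 0.981), the EGFR family with fry (0.215), neuroendocrine markers with DESeq2 (0.968), the GC trend removed (0.961) and fry (0.0569), and the BCL2 family without control replicate 1 (from 0.820 to 0.978 without 1 library). The p53 targets turned with edgeR (0.979), the GC trend removed (0.956), the length trend removed (0.982), fry (0.698) and without control replicate 1 (from 0.859 to 0.978 without 1 library). The cause was not tested. In simulated data with 3 libraries per group and 200 genes changed among 14488 tested, 32.8% of the genes changed 1.5-fold were recovered. In the real comparison 7785 of 15229 genes were called, which makes the adjusted threshold less strict. The simulated share therefore does not tell how often small changes were missed here.

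With the replicate number as a replicate block, 4438 genes were higher and 3552 lower. With the block and the GC trend removed, ERBB2 was called higher (adjusted p = 0.0165). With the block, the p53 targets turned direction when the GC trend (adjusted p = 0.984) or the length trend (0.994) was also removed. The labels do not say that the numbers pair the libraries, and the reported test does not use them. The deviations of same-numbered libraries correlated at 0.137, 0.0725 and 0.111 across genes, and those of differently numbered ones at -0.139 to 0.0984. Each gefitinib library correlated best with the control of its number, but control replicate 2 correlated best with gefitinib replicate 3 (0.0984). Whether the libraries are paired stays open.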

Other observations

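The gene families here, the test of the hypothesis on the integrated stress response, the tests over all immediate early members and the comparison of divergent pairs with distant pairs were chosen after the results were seen. Keratin genes, structural genes of epithelial cells, were lower as a family: of 18 tested, 15 fell and 0 rose by limma, with 15 and 0 by edgeR and with TMM factors, and between 11 and 15 fell without 1 library. KRT23 fell from 3365 to 491 mean normalized reads (n = 3), KRT16 from 2449 to 533 and KRT34 from 111 to 11.6. Genes of respiratory complex I moved the other way, with 24 of 45 higher and 2 lower (20 and 2 with TMM factors); NDUFA5 rose by 1.47 ± 0.16 (SE) on the log2 scale and NDUFA2 by 1.48 ± 0.17. Of 18 histone genes 11 rose and 1 fell, with H1FX going from 103 to 557 and HIST1H2BD from 83.4 to 293, and of 418 zinc finger genes of the ZNF series 196 rose and 81 fell (183 and 90 with TMM factors), among them ZNF654 at 2.52 ± 0.13 and ZNF704 at -1.49 ± 0.08. The camera adjusted p over 14 families was 3.23e-05 for keratins, 0.00347 for complex I, 0.0144 for histones and 0.0175 for the ZNF genes. With an estimated correlation the adjusted p was 0.702 for keratins, complex I and histones and 0.809 for the ZNF genes. The other 10 families were not past the threshold, among them solute carriers (60 of 205 higher, 64 lower), proteasome subunits (8 of 36 higher, 12 lower), heat shock proteins (22 of 57 higher, 17 lower) and cytosolic tRNA synthetases (5 of 20 higher, 8 lower). For proteasome subunits the counts were 5 higher and 5 lower without gefitinib replicate 2, and 8 and 14 without control replicate 1.

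The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 4312 genes higher, 3473 lower and 3397 changed at least 2-fold, and in each of these counts 1 split, the real one, reached its value. The highest of the other 9 was 0 by limma and 0 by edgeR, with at most 307 genes at an unadjusted limma p under 0.05. Each of these 9 splits mixes control and gefitinib libraries, so the difference between the groups widens the spread within each side. Counts of 0 there were close to fixed in advance and say little on calls by chance. For the gene lists called by camera the real split gave 8 and the highest other split 7, and 1 split, the real one, reached 8.

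Of 24 immediate early genes 15 rose and 3 fell, and of 18 MAP kinase output genes 10 fell and 4 rose; both list calls were lost with an estimated correlation (adjusted p = 0.707). The 15 that rose, picked with all libraries, had a median log2 difference of 2.39, and it was 2.39 after removal of the GC trend, 2.35 after removal of the length trend and at lowest 2.27 without 1 gefitinib library. Over all 24 members the median of 0.94 became 0.94, 0.88 and 0.89. The share kept lay above 0.5 (95% bootstrap intervals from 0.890 to 1.01, 0.693 to 0.987 and 0.702 to 0.987). Across genes the log2 differences hardly followed GC content or transcript length (Spearman correlations of -0.0571 and -0.00413). Removing either trend could therefore hardly have halved the median. For the left-out library a bound of 0.75 was set first, missed and eased after the interval was seen. The median did not rest on 1 gefitinib library alone, but without control replicate 1 it was 0.67, with 14 members higher and 4 lower. No conclusion on a cause is drawn from these values, and a part played by 1 culture or by the length trend is not excluded. A hypothesis is that a stress-type response, which would include the integrated stress response genes, may contribute; that list was higher by camera (adjusted p = 0.00197) but had adjusted p = 0.707 with an estimated correlation, so it stays open. Gefitinib itself, the handling of the treated cultures and a possible difference in serum are the same contrast in this design and were not separated.

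Some kinds of close neighbours in the genome had weakly correlated changes. Across gene pairs within 5 kb, which are not independent replicates, the Pearson correlation of log2 differences was 0.0995 (95% interval from 0.0320 to 0.168) over 1016 pairs in tandem and 0.149 (0.0606 to 0.241; permutation p = 2e-04, 5e-04 adjusted over 5 kinds of pair) over 577 pairs with divergent starts, but 0.0256 (-0.0548 to 0.106; permutation p = 0.517) over 627 convergent pairs, and it was 0.0651 over 1570 overlapping pairs. Reads counted in a neighbour on the same strand were set beforehand to lift the tandem value above the divergent one by 0.1 or more. The tandem value lay below the divergent one, though their intervals overlap. It also lies under the bound of 0.1 set beforehand for no such effect, but its interval spans that bound. Such reads therefore cannot be told apart from no such effect. The divergent value passed its own bound set beforehand, but 7775 pairs of neighbours farther apart correlated at 0.0909 (0.0675 to 0.115), whose interval overlaps; that comparison was added after the distant pairs were seen, because they correlated as well, so a shared response of divergent genes may exist and was not separated from the broader correlation.

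Mitochondrial transcripts varied within groups, from 1.07% to 2.34% of the reads in control and from 1.67% to 3.07% in gefitinib libraries. Leaving them out of the totals lost 0.668% of the 7785 calls, under the bound of 10% set beforehand. The calls thus hardly depended on whether these transcripts were counted in the totals. Shares this small move the totals little, and TMM factors, a rescaling of all genes, still kept 7372 of the calls. That bound could therefore hardly have been reached, and no conclusion on a cause is drawn from it. No biological explanation was tested.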
